A study of Homo sapiens with 9 samples.

How the data were processed

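RNA was sequenced from cells labelled MCF-7, in 9 libraries that the labels place in 3 groups of 3. The groups were untreated cells at 0 h and cells given 10 µM GlyH-101 for 1 h or for 24 h. Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

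The authors deposited 1 table of FPKM values (fragments per kilobase of gene per M mapped reads), with 58977 rows and a column per library. The submitters' processing notes name CASAVA, TopHat2 2.0.7, Bowtie2, HTSeq and DESeq 1.18.0, without saying which step each served. The genome build, the annotation and the use of strand are not given in the sources used here, so no coordinates are printed, and genes that overlap an antisense partner cannot be separated from it. Of the rows, 58395 carry an Ensembl gene ID and 582 an ID of another form. A symbol was found for 57754 of the Ensembl IDs in a table of gene names, and for 521 more in GENCODE 29, which left 120 without one. All 649 list members were matched. A library's FPKM depends on the gene length and on the total used by the authors, and their annotation decides how reads of near-identical genes were split.

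Depth was read from the steps in low values. Genes with 1 exon in GENCODE 29 had FPKM values that were whole multiples of the value of 1 read, and 99.9 to 100.0 percent of values of up to 20 reads came out whole within a tolerance of 0.05 read. The total behind each library was then 43.1, 44.6 and 46.9 M reads at 0 h, 47.1, 46.2 and 43.9 M at 1 h, and 43.9, 44.2 and 45.4 M at 24 h. In a gene of 1 kb, 1 read was worth between 0.0213 and 0.0232 FPKM. The steps did not give whole reads for genes with several exons, whose length in the authors' annotation is unknown, so no count test was run.

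Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with lmFit and eBayes with an intensity trend. Genes with FPKM of at least 1 in at least 3 of the 9 libraries were kept, which gave 14689 genes. All 9 libraries entered 1 fit with 6 residual degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. A ratio described as a fold is the ratio of mean FPKM.

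Before the data were examined, 28 gene lists were fixed from general knowledge, together with the tests, the alternatives and the rule for named genes. Each list was tested with camera at its preset correlation of 0.01, adjusted over the lists and the 3 comparisons together, and again with an estimated correlation. The rule for named genes took, for each time against 0 h, the 10 called genes with the largest rise and the 10 with the largest fall, among those with a mean of FPKM 5 or more in the higher group and no overlap between the replicates. For 24 h against 1 h it took 5 in each direction, and it passed over predicted loci, clones, small RNAs and antisense genes. The rule added up to 2 called members per list and direction, and a fixed set comprising CFTR, ESR1, PGR, GREB1, TFF1, CCND1, MYC, FOS, EGR1, CYP1A1, HMOX1, DDIT3, ATF3, CDKN1A, MKI67, ACTB and GAPDH. Not every gene that qualified is described. XIST and genes of the Y chromosome were left out of the gene table.

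The fit was tested on simulated data with 50 changed genes at each size of change. For 1 h against 0 h it recovered 34, 68, 94 and 100 percent of the genes changed by 0.25, 0.5, 1 and 2 on the log2 scale. It made 10 false calls among those of the 14689 genes left unchanged. For 24 h against 0 h it recovered 44, 68, 90 and 96 percent, with 5 false calls. In the real data 24.5 percent of genes were called at 1 h and 58.7 percent at 24 h, far more than were changed here. Recovery and false calls after Benjamini-Hochberg adjustment depend on that share, so these numbers need not hold for the real calls. A simulated shift of 1 list by 0.3 was called by camera, and 0 of the other 27 lists were. Genes varied independently in these simulations, so they do not test camera on correlated genes.

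Replicates were compared before they were averaged. Log2 values correlated at 0.9926 to 0.9939 between replicates of a group and at 0.9654 to 0.9819 between groups. In single-exon genes with recovered reads, each pair of replicates differed by more than sampling noise, with a chi-square per gene between 3.09 and 3.81. Library preparation alone could give such a spread, so it does not show that the replicates were separate cultures. The 9 libraries were treated as separate replicates because the labels number them so. The first principal component held 52.9 percent of the variance and set 24 h apart from the other times, and the second held 23.6 percent and set 0 h apart from 1 h.

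The alternatives tried were pseudocounts of 0.1 and 1, no filter on low FPKM, a mean of at least FPKM 5, median-of-ratios scaling, quantile normalization, no intensity trend, only the 2 groups compared, a replicate block, library weights and each library left out in turn. Rescaling each library to TPM, which gives every library the same sum, was added after seeing the data. Overlap of the calls at the 2 times was set beside 100 simulations of unchanged groups that share the 0 h libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.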

Results

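The series measured gene expression in 9 RNA-seq libraries from cells labelled MCF-7, a luminal, estrogen receptor-positive breast cancer line. The cells had been exposed to GlyH-101, a glycine hydrazide that blocks the pore of the chloride channel CFTR. There were 3 libraries each from untreated cells at 0 h and from cells given 10 µM for 1 h or for 24 h. Between 43.1 and 47.1 M reads lay behind each library, and 13939 to 14179 genes per library reached FPKM 1. Depth differed little between groups. None of the 9 libraries is labelled as vehicle-treated, so each comparison with 0 h holds the drug together with elapsed time, vehicle and handling.

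Several transcripts that mark luminal MCF-7 cells were near 0 in the untreated libraries, others were abundant, and so were several mesenchymal and basal markers. ESR1, the estrogen receptor, had a mean of 0.296 ± 0.059 FPKM (SD, n = 3). The luminal transcription factor GATA3 was at 0.22 ± 0.047 FPKM, E-cadherin (CDH1) at 0.461 ± 0.017, KRT19 at 0.263 ± 0.265 and EPCAM at 0.844 ± 0.178. PGR and GREB1, which are estrogen receptor targets, were at 0.005 ± 0.004 and 0.292 ± 0.078 FPKM, and TFF1 was listed at 0 in all 9 libraries. The intermediate filament gene VIM was at 199.6 ± 6.35 FPKM, N-cadherin (CDH2) at 21.9 ± 0.531, FN1 at 128.5 ± 4.78 and EGFR at 88.1 ± 1.06. The simple epithelial keratins KRT8 and KRT18 were at 1630 ± 35.6 and 466.4 ± 10.0 FPKM, and among further luminal genes CXXC5 was at 192.3 FPKM, TBX3 at 77.8 and SLC39A6 at 35.5. CDKN2A, which MCF-7 lacks through a homozygous deletion, was at 622.6 ± 44.95 FPKM and at 567.3 or more in every library. Of the 19 luminal genes fixed beforehand 9 passed the expression filter, against 15 of 19 fibroblast and mesenchymal genes, 9 of 14 basal and squamous genes and 2 of 16 blood and endothelial genes. CDKN2A, CXXC5, TBX3, SLC39A6 and the members of these lists named here were chosen after their values were seen, except ESR1, which was fixed beforehand. The libraries are therefore described by their label throughout, and the line was not identified.

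**Figure D1:**
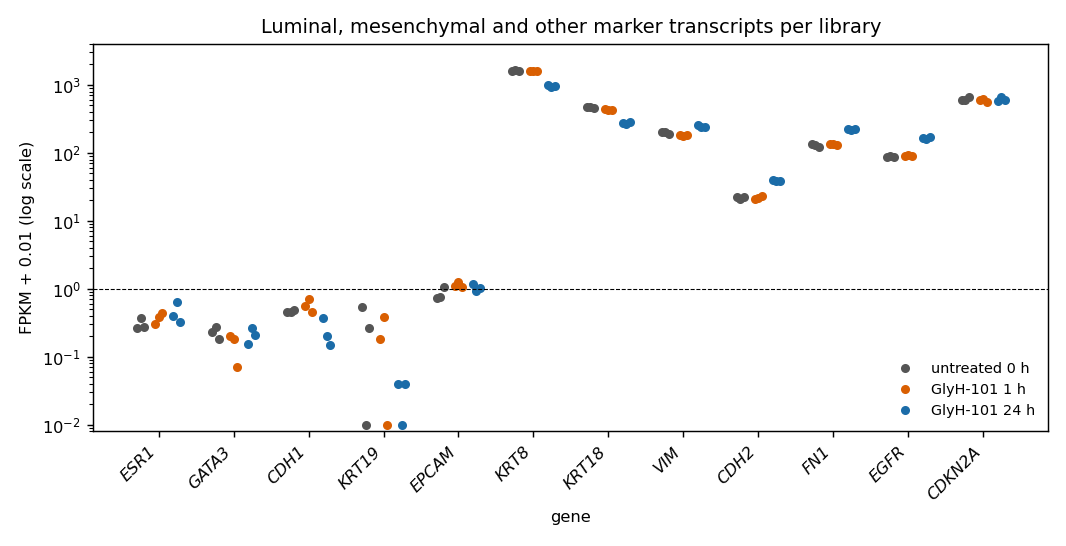
FPKM + 0.01 on a log axis for 12 marker genes in each of the 9 libraries, colored by group, with a dashed line at FPKM 1. ESR1, GATA3, CDH1, KRT19 and EPCAM stay at or under 1.256 FPKM in every library, and CDKN2A stays at or above 567.3.

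CFTR, the target of the compound, was close to 0 in every library, with 0.201 FPKM as its highest value. Mean CFTR was 0.077 ± 0.069 FPKM at 0 h (SD, n = 3), 0.147 ± 0.051 at 1 h and 0.027 ± 0.035 at 24 h, which the filter left out. In the fit without the filter CFTR was not called at 1 h or 24 h against 0 h or between the times (log2 fold changes 0.17, -0.12 and -0.30, SE 0.097, adjusted p = 0.423, 0.457 and 0.0613). Among 31 chloride channel and transporter genes 21 were tested. At 1 h 3 rose and 4 fell, or 3 and 5 adjusted over the list alone, with LRRC8A up by 0.31 on the log2 scale and SLC26A6 down (log2 fold change -0.37). At 24 h 10 rose and 4 fell, the same adjusted over the list alone, among them CLIC4 (log2 fold change 0.81) and SLC26A2 (-0.57). The list did not stand apart from other genes by camera at either time (adjusted p = 0.818 and 0.102), although at 24 h it passed in the fit without the filter (0.0232).

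The comparison of 1 h with 0 h asked which transcripts changed soon after the compound was added. Immediate early genes rose together, and every one of the 34 members tested was higher at 1 h (34 adjusted over the list alone), with a median log2 fold change of 2.10. EGR1 (ENSG00000120738), a zinc finger transcription factor induced by growth factors and stress, went from 1.84 ± 0.042 to 263.6 ± 23.1 FPKM (SD, n = 3), a 142.9-fold change (log2 fold change 6.81, SE 0.077, limma adjusted p = 3.76e-13). NR4A1, an orphan nuclear receptor, went from 37.6 ± 1.93 to 1151 ± 24.9 FPKM. The matricellular genes CCN2 and CCN1 went from 2.63 ± 0.276 to 340.0 ± 3.45 and from 56.0 ± 3.39 to 1636 ± 43.9 FPKM. FOSB and the ERK phosphatase gene DUSP5 were also among the 10 largest rises (log2 fold changes 5.51 and 5.62). So were EGR2, from 0.008 ± 0.007 to 22.6 ± 0.927 FPKM, and EGR3, from 0.033 ± 0.039 to 15.5 ± 0.51.

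Inflammatory genes rose alongside. Of 17 NF-kB target genes tested 16 were higher at 1 h and none lower, the same adjusted over the list alone, with a median log2 fold change of 1.28. The chemokine gene CXCL8 went from 0.076 ± 0.097 to 54.2 ± 4.23 FPKM and the cytokine gene IL6 from 1.19 ± 0.207 to 71.6 ± 3.14 (SD, n = 3). YAP/TEAD targets rose in 8 of 14 cases with 0 falls (8 and 2 adjusted over the list alone), led by CCN2 and CCN1, which the immediate early list also holds. Among p53 targets 9 of 25 rose and 3 fell, the same adjusted over the list alone, with GDF15 up by 1.93 and GADD45A by 1.87 on the log2 scale. The other 13 p53 targets were not called, and the median log2 fold change was 0.047 against a mean of 0.327. BTG2 belongs to the immediate early list as well. These 4 lists passed camera (adjusted p = 8.08e-75, 2.40e-30, 4.65e-10 and 7.05e-05) and kept their calls with an estimated correlation (adjusted p = 0.00169, 0.00697, 0.00735 and 0.0207).

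Of the fixed set of genes, ATF3 was 13.9-fold higher at 1 h (log2 fold change 3.76), FOS 3.64-fold (1.83), MYC 1.51-fold (0.60) and CDKN1A, which encodes the cell cycle inhibitor p21, 1.43-fold (0.52). ACTB rose by 0.34 on the log2 scale. CCND1 (log2 fold change 0.07, adjusted p = 0.142), GAPDH (-0.07, 0.075), DDIT3 (0.22, 0.0635) and CYP1A1 (0.49, 0.0672) did not pass. Without untreated 0 h replicate 2, GAPDH and DDIT3 passed (adjusted p = 0.0423 and 0.00629), and without untreated 0 h replicate 1, CYP1A1 did (0.0171). Median-of-ratios scaling also brought CCND1 and DDIT3 past the threshold (0.0203 and 0.0307). DDIT3 passed after quantile normalization (0.0387) and among genes with a mean of at least FPKM 5 (0.0490) as well, and CYP1A1 after quantile normalization (0.0485) and with library weights (0.0453).

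Aryl hydrocarbon receptor targets were higher in 3 of 7 cases, with none lower (4 and 0 adjusted over the list alone). TIPARP rose by 2.47 and CYP1B1, a xenobiotic-metabolizing enzyme, by 1.88 on the log2 scale. The list passed camera (adjusted p = 2.67e-05), but with adjusted p = 0.0743 when the correlation was estimated. In the hypoxia list 10 of 25 rose and 3 fell, the same adjusted over the list alone. The mean log2 fold change was 0.12 and the median -0.01, so mean and median differed in sign (camera upward, adjusted p = 0.00337, and 0.112 with an estimated correlation). ADM rose by 1.15 on the log2 scale and DDIT4, an mTORC1 inhibitor gene, went from 476.0 ± 48.3 to 239.7 ± 3.34 FPKM. Estrogen receptor targets moved apart in the same way, with 5 of 26 higher and 4 lower, the same adjusted over the list alone, a mean of 0.37 and a median of -0.002. That list passed camera upward (adjusted p = 0.0192, and 0.169 with an estimated correlation), and not without GlyH-101 1 h replicate 1 or 2 (0.0907 and 0.0973). EGR3 and AREG, its highest members, respond to growth factor signaling as well, and ESR1 itself lay under the filter. Fibroblast and mesenchymal markers had 3 of 15 higher and 1 lower, the same adjusted over the list alone (camera upward, adjusted p = 0.0287, and 0.119 with an estimated correlation). SNAI2 rose by 0.76 on the log2 scale, and the list's call was lost without untreated 0 h replicate 1 (0.0752) or GlyH-101 1 h replicate 1 (0.0511).

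Large falls at 1 h were few. TXNIP, a regulator of glucose uptake with a short-lived mRNA, went from 26.8 ± 0.481 to 6.15 ± 0.678 FPKM (log2 fold change -2.04, SE 0.066, limma adjusted p = 2.11e-09). The homeobox genes OTX1 and HOXC11 fell by 1.40 and by 0.93 on the log2 scale. The adaptor gene GRB7 dropped by 1.03, ARL4D by 0.99, CLDND2 by 1.06, MTMR11 by 0.93 and ZNF48 by 0.93. ARL17B fell by 1.13 (adjusted p = 0.0276), but its reads can be shared with a near-identical paralog. Its call was lost without untreated 0 h replicate 2 or 3 (0.0851 and 0.0697) or GlyH-101 1 h replicate 2 or 3 (0.0974 and 0.0822). The ARL17B call was also lost without the filter (0.126), without the intensity trend (0.0674) and with a replicate block (0.0512).

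Small decreases were found in some proliferation and housekeeping lists and not in others. DNA replication and G1/S genes had 1 of 29 higher and 3 lower, or 0 and 3 adjusted over the list alone (camera adjusted p = 0.916), and glycolysis genes 2 of 18 higher and 3 lower, the same adjusted over the list alone (0.418). Mitotic and G2/M genes fell in 20 of 28 cases with no rise (23 adjusted over the list alone), by a median of -0.19 on the log2 scale (camera adjusted p = 9.08e-08, and 0.261 with an estimated correlation). TOP2A fell by 0.33 and MKI67 by 0.19. Cytosolic ribosomal protein genes fell in 26 of 44 cases (30 adjusted over the list alone), with a median of -0.09. Nuclear oxidative phosphorylation genes fell in 10 of 32 cases (13 adjusted over the list alone), with a median of -0.10. After median-of-ratios scaling these 3 lists held 13, 9 and 6 falls and still passed camera. The ribosomal and oxidative phosphorylation calls held with an estimated correlation (adjusted p = 0.0343 and 0.0325). Heat shock genes had 5 of 18 lower and 1 higher, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0147, and 0.189 with an estimated correlation). The heat shock call was lost after median-of-ratios scaling (0.0617).

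In all, limma called 3593 of 14689 genes at 1 h, 1197 higher and 2396 lower, so that 66.7 percent of the calls were falls. Most calls were small, with 220 higher and 54 lower by 2-fold or more. The balance depended on scaling. Median-of-ratios scaling, which centers the median fold change, gave 1675 higher and 1362 lower, or 44.8 percent falls, while quantile normalization and rescaling to TPM left 57.4 and 57.8 percent. The 2-fold counts at 1 h were 124 higher and 10 lower among genes with a mean of at least FPKM 5, and the falls by 2-fold numbered 118 with a pseudocount of 0.1 and 27 with 1.

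**Figure D2:**
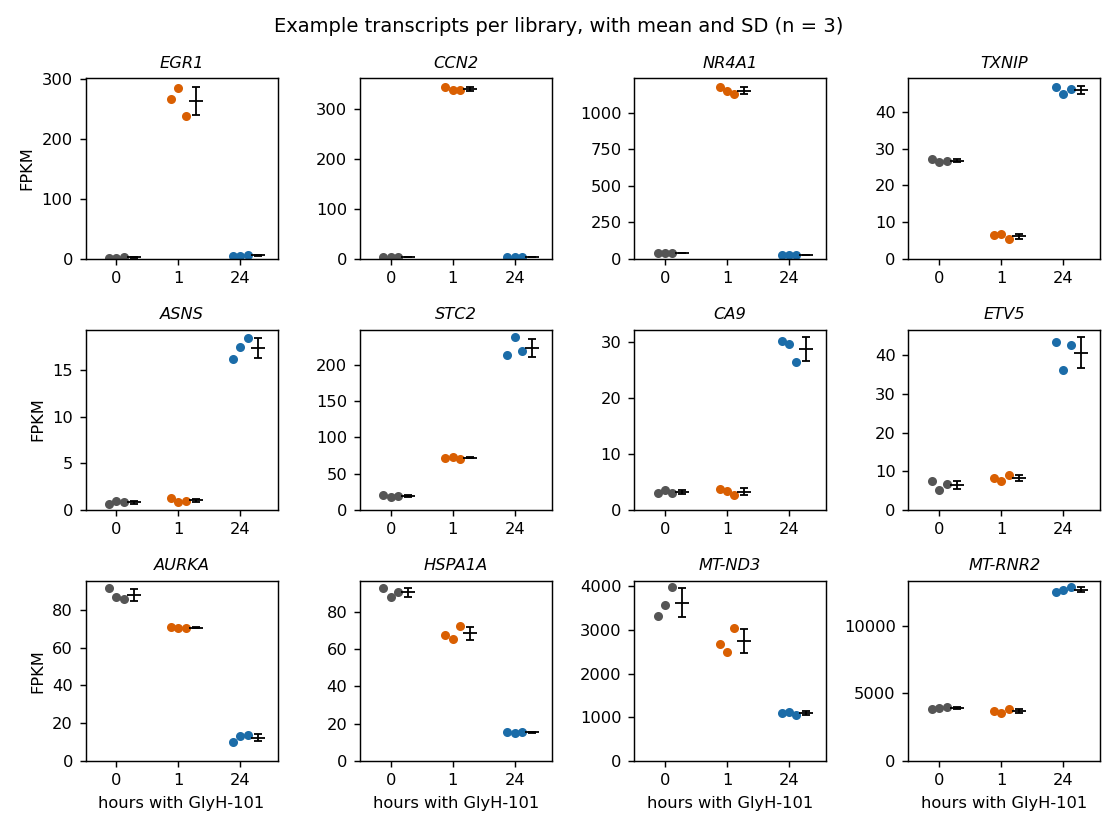
FPKM of 12 genes in each library at 0, 1 and 24 h with GlyH-101, each panel on its own linear axis from 0, with the mean and SD (n = 3) beside the points. EGR1, CCN2 and NR4A1 peaked at 1 h, ASNS, STC2, CA9 and ETV5 were highest at 24 h, and AURKA, HSPA1A and MT-ND3 were lowest there.

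The comparison of 24 h with 0 h asked what a day of exposure left. Genes of the integrated stress response, which the transcription factor ATF4 drives, were higher in 31 of 32 cases (31 adjusted over the list alone), with a median log2 fold change of 1.75. ASNS (ENSG00000070669), asparagine synthetase, went from 0.804 ± 0.185 to 17.4 ± 1.11 FPKM (SD, n = 3), a 21.7-fold change (log2 fold change 3.79, SE 0.133, limma adjusted p = 2.84e-09). CHAC1, which degrades glutathione, went from 1.82 ± 0.311 to 29.1 ± 2.55 FPKM, and the secreted glycoprotein gene STC2 from 18.9 ± 0.843 to 223.9 ± 12.6. TRIB3 rose by 2.83, the cystine transporter gene SLC7A11 by 2.65 and DDIT3, which encodes CHOP, by 2.34 on the log2 scale. ATF5 was the member that fell, from 21.0 ± 0.599 to 8.10 ± 0.429 FPKM. The list passed camera (adjusted p = 3.06e-19, and 0.00169 with an estimated correlation), and ADM2, outside the list, rose by 3.58.

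Endoplasmic reticulum chaperones did not rise with it as a list. Of 20 genes 9 were higher and 7 lower, the same adjusted over the list alone (median 0.03, camera adjusted p = 0.279). HERPUD1 rose by 1.179 and XBP1 by 0.94 on the log2 scale, while SDF2L1 fell by 0.58 and CRELD2 by 0.47.

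Hypoxia response genes were higher in 23 of 25 cases and lower in 2, the same adjusted over the list alone, with a median log2 fold change of 0.75. The carbonic anhydrase gene CA9 went from 3.21 ± 0.332 to 28.7 ± 2.08 FPKM and ANGPTL4, a lipase inhibitor, from 3.30 ± 0.321 to 26.5 ± 0.954, while ADM and PFKFB4 fell by 1.009 and by 0.59. Targets of p53 were higher in 22 of 25 cases and lower in 2, the same adjusted over the list alone, with a median of 0.59. GDF15 rose by 2.04 and SESN2 by 1.88, and both belong to the integrated stress response list as well. Both lists passed camera (adjusted p = 7.31e-09 and 6.31e-08) and held with an estimated correlation (adjusted p = 0.0141 and 0.00866). Glycolysis genes were higher in 11 of 18 cases and lower in 3, the same adjusted over the list alone, led by the glucose transporter gene SLC2A1 (log2 fold change 1.19). The glycolysis list only just passed camera (adjusted p = 0.042, and 0.34 with an estimated correlation). It did not pass without untreated 0 h replicate 1 or 2 (0.0529 and 0.0566), without GlyH-101 24 h replicate 1 (0.0508), without the intensity trend (0.062) or among genes with a mean of at least FPKM 5 (0.0826).

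Heat shock genes fell without exception at 24 h. All 18 tested members were lower (18 adjusted over the list alone), with a median log2 fold change of -0.97 (camera adjusted p = 3.18e-14, and 0.00866 with an estimated correlation). The HSP70 genes HSPA1A and HSPA1B went from 90.4 ± 2.35 to 15.2 ± 0.303 and from 53.3 ± 1.16 to 11.2 ± 0.366 FPKM (SD, n = 3). They are nearly identical in sequence, so the split of reads between them is uncertain. The fall of the list held under each scaling tried.

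Mitotic and G2/M genes were lower in 27 of 28 cases with no rise (27 adjusted over the list alone), with a median of -0.66. The mitotic kinase gene AURKA went from 88.0 ± 3.05 to 12.3 ± 2.03 FPKM (log2 fold change -2.81, SE 0.091, limma adjusted p = 1.68e-09) and the cyclin gene CCNB1 from 226.6 ± 2.57 to 51.4 ± 5.54. The list passed camera (adjusted p = 4.96e-15) but with adjusted p = 0.144 when the correlation was estimated. MKI67 fell by 0.11 (adjusted p = 0.0371). That call was lost without untreated 0 h replicate 1 or 2 (0.12 and 0.0841), GlyH-101 1 h replicate 1 or 2 (0.0500404 and 0.0506) or GlyH-101 24 h replicate 2 (0.109), after quantile normalization (0.159), after rescaling to TPM (0.231), without the intensity trend (0.0793), without the filter (0.0979) and with only the 2 groups compared (0.0682). DNA replication and G1/S genes went both ways, with 8 of 29 higher and 13 lower, the same adjusted over the list alone (camera adjusted p = 0.101, and 0.0204 without the filter). POLA1, the catalytic subunit of DNA polymerase alpha, fell by 2.39 and the sliding clamp gene PCNA by 1.80, while the licensing factor gene CDT1 rose by 0.82 and E2F1 by 0.47.

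Mitochondrial transcripts split by type at 24 h. All 13 mitochondrially encoded mRNAs were lower (13 adjusted over the list alone), with a median log2 fold change of -0.74, and MT-ND3 went from 3625 ± 335.9 to 1089 ± 43.5 FPKM. After quantile normalization 12 were lower and 1 higher, and after rescaling to TPM 12 were lower. The list passed camera (adjusted p = 6.09e-08) but with adjusted p = 0.116 when the correlation was estimated. The mitochondrial ribosomal RNAs, chosen after their values were seen, went the other way. MT-RNR1 rose from 642.5 ± 27.2 to 2961 ± 68.5 FPKM (log2 fold change 2.20, SE 0.042, limma adjusted p = 4.21e-11) and MT-RNR2 from 3917 ± 76.7 to 12667 ± 193.2 (1.69). Nuclear oxidative phosphorylation genes were lower in 22 of 32 cases and higher in 1 (24 and 1 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 1.60e-06, and 0.00937 with an estimated correlation). CYCS, which encodes cytochrome c, fell by 1.33. Cholesterol synthesis genes were lower in 19 of 26 cases and higher in 4, the same adjusted over the list alone, with IDI1 down by 0.74 (log2 fold change -0.74) and PCSK9 up by 0.94 (camera adjusted p = 0.00063, and 0.0713 with an estimated correlation).

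Other single genes with large changes at 24 h were PSG4, a pregnancy-specific glycoprotein gene, and PZP, an alpha-2-macroglobulin relative, which went from 43.2 ± 1.31 to 4.43 ± 0.395 and from 30.9 ± 1.81 to 4.02 ± 0.381 FPKM. The myosin kinase gene MYLK3 fell by 2.23, the Wnt inhibitor gene DKK1 by 2.13 and the pseudogene TPT1P12 by 2.33. PSG4 and TPT1P12 have close sequence relatives and are uncertain for that reason. The transcription factor gene ETV5, a known ERK target, rose by 2.58. In the fixed set, ATF3 (log2 fold change 1.67), EGR1 (1.28), CYP1A1 (1.23), CDKN1A (0.84), MYC (0.46) and GAPDH (0.20) were higher, and FOS (-0.75), HMOX1 (-0.71) and ACTB (-0.34) lower. HMOX1 had been lower at 1 h too (-0.29, adjusted p = 0.00322). CCND1 rose by 0.11 (adjusted p = 0.017), a call lost without untreated 0 h replicate 2 (0.072) or GlyH-101 24 h replicate 1 (0.0648). ESR1 stayed at 0.446 ± 0.162 and GREB1 at 0.501 ± 0.106 FPKM at 24 h, and PGR was listed at 0 in the 3 libraries.

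Cell type markers also moved at 24 h, in mixed directions. KRT8 and KRT18 fell by 0.76 and by 0.75 on the log2 scale, CDH2 rose by 0.82, FN1 by 0.78, EGFR by 0.90 and KRT17 by 1.41, and PDGFRB fell by 1.22. Fibroblast and mesenchymal markers had 10 of 15 higher and 5 lower, basal and squamous markers 5 of 9 higher and 2 lower, luminal genes 1 of 9 higher and 4 lower, and blood and endothelial markers 1 of 2 higher and 1 lower. The counts were the same adjusted over the list alone, and none of the 4 lists passed camera (adjusted p = 0.213, 0.232, 0.246 and 0.509).

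The remaining lists went both ways at 24 h and most did not pass camera. Immediate early genes were the exception, with 21 of 34 higher and 7 lower, the same adjusted over the list alone (median 0.38, camera adjusted p = 0.000881, and 0.169 with an estimated correlation). NF-kB targets had 8 of 17 higher and 5 lower, or 9 and 6 adjusted over the list alone (0.509). Counts adjusted over the list alone were the same as over all genes for the next 8 lists. YAP/TEAD targets had 4 of 14 higher and 8 lower (0.148), aryl hydrocarbon receptor targets 5 of 7 and 2 (0.095), estrogen receptor targets 12 of 26 and 6 (0.156) and NRF2 targets 7 of 19 and 8 (0.705). Interferon-stimulated genes had 10 of 21 higher and 4 lower (0.214), BCL2 family and caspase genes 12 of 23 and 3 (0.0818), lysosome and autophagy genes 8 of 24 and 10 (0.623), and fatty acid synthesis genes 6 of 14 and 8 (0.47). In the fit without the filter YAP/TEAD, aryl hydrocarbon receptor and estrogen receptor targets and BCL2 family genes passed (0.0238, 0.0272, 0.0407 and 0.0105). The pro-apoptotic genes PMAIP1 and BBC3 rose by 1.86 and by 1.51 on the log2 scale. Metallothionein and zinc response genes had 1 of 6 higher and 3 lower, the same adjusted over the list alone (0.275). Ribosomal protein genes had 5 of 44 higher and 14 lower, or 5 and 13 adjusted over the list alone (median -0.03, adjusted p = 0.215). That balance turned after quantile normalization, to 19 higher and 4 lower (median 0.063), and after rescaling to TPM, to 14 higher and 9 lower (median 0.018).

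At 24 h limma called 8622 of 14689 genes, 4488 higher and 4134 lower, of which 323 and 239 changed by 2-fold or more. Among genes with a mean of at least FPKM 5, the 2-fold counts were 181 and 120, and the falls numbered 383 with a pseudocount of 0.1 and 154 with 1.

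**Figure D3:**
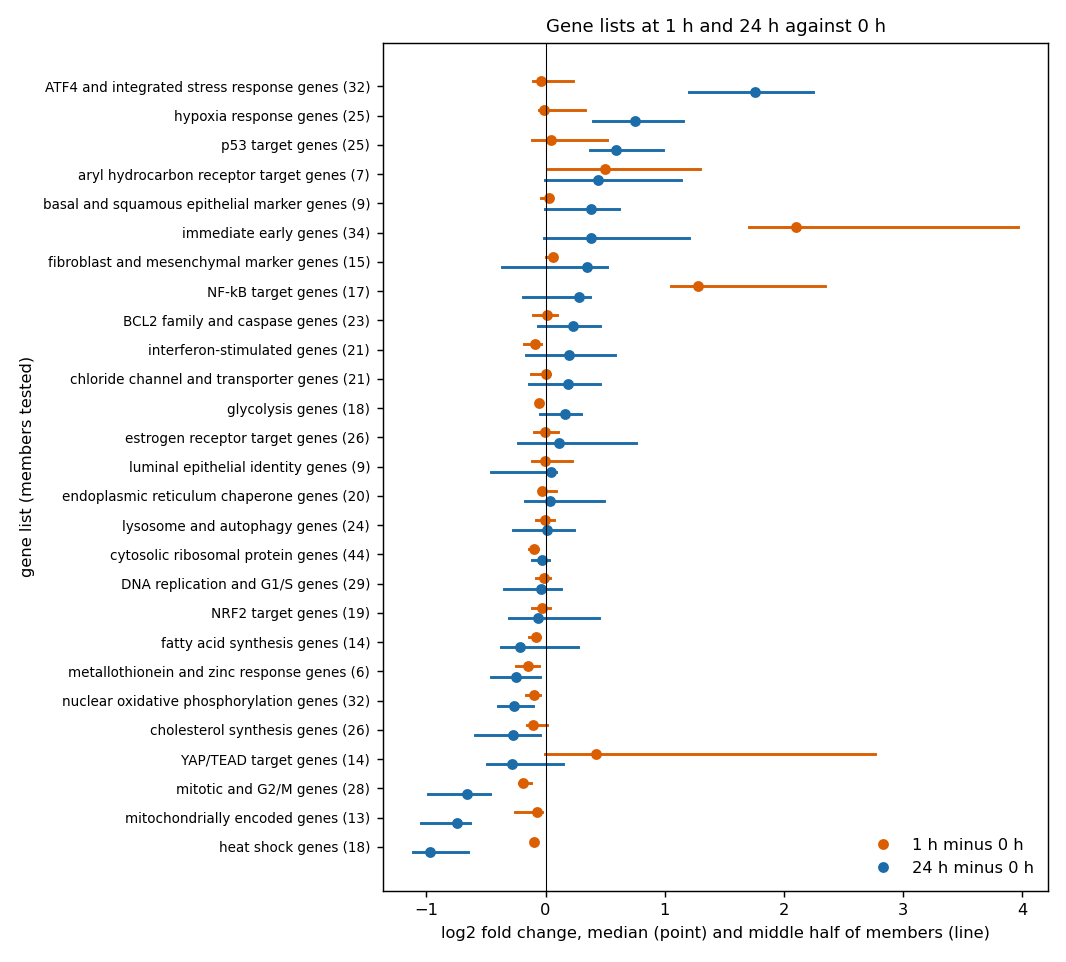
Median log2 fold change (points) and interquartile range of the members (lines) for the lists with 5 or more genes tested, at 1 h (orange) and 24 h (blue) against 0 h. Immediate early genes had a median of 2.10 at 1 h and 0.38 at 24 h, and integrated stress response genes -0.04 and 1.75.

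The comparison of 24 h with 1 h asked what the early response turned into. Immediate early genes fell in 31 of 34 cases (31 adjusted over the list alone), with a median of -2.08, and 1, KLF4, rose by 0.83. CCN2 went from 340.0 ± 3.45 back to 2.67 ± 0.437 FPKM (SD, n = 3), CXCL8 from 54.2 ± 4.23 to 0.212 ± 0.184 and EGR1 from 263.6 ± 23.1 to 5.22 ± 0.545. CCN1 and NR4A1 fell by 5.65 and by 5.41 on the log2 scale. NF-kB targets fell in 15 of 17 cases, the same adjusted over the list alone, and YAP/TEAD targets in 10 of 14 (10 adjusted over the list alone). Integrated stress response genes rose in 30 of 32 cases between the times (31 adjusted over the list alone), with ASNS, ADM2 and CHAC1 up by 3.59, 3.59 and 3.41 on the log2 scale, TRIB3 by 3.19 and CA9 by 2.99. These 4 lists passed camera (adjusted p = 1.38e-21, 2.52e-10, 3.36e-05 and 9.15e-16) and held with an estimated correlation (adjusted p = 0.00866, 0.0325, 0.0207 and 0.00205). Limma called 9043 genes between the times, 5305 higher and 3738 lower, of which 383 and 369 changed by 2-fold or more. Among genes with a mean of at least FPKM 5, the 2-fold counts were 187 and 200.

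Most genes that rose by 2-fold or more at 1 h had moved down from that level by 24 h. Of 220 genes higher by 2-fold or more at 1 h, 196 were lower at 24 h than at 1 h, and 99 were still called higher than at 0 h, 42 were called lower and 79 were not called. Of 54 genes lower by 2-fold or more at 1 h, 31 were higher at 24 h than at 1 h, and 22 were still called lower than at 0 h, 3 were called higher and 29 were not called. Over all calls, 635 genes were higher at both times and 972 lower at both, against 366 and 674 for independent lists. Simulated unchanged groups gave an overlap of 0, which their lack of calls fixes and which is no measure of the shared libraries. Another 257 were higher at 1 h and lower at 24 h and 618 the reverse, against 337 and 732 for independent lists. The 1 h and 24 h fold changes correlated across genes at r = 0.214, against 0.498 for simulated unchanged groups that share the 0 h libraries, and genes are not independent replicates. Their covariance was 0.0371 against a simulated 0.0109, a difference of 0.0262. Part of the overlap beyond that of independent lists may come from the 3 shared untreated libraries, which are too few to be split.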

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

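Of the tests weighed here, those of loss under the drug, admixture, CDKN2A, poly(A) selection, all mitochondrial RNA and scaling were chosen only after the results were seen.

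The following lists stood out because the test of 24 h against 1 h itself passed, so the responses at the 2 times differed. Median log2 fold changes between the times were -2.076 for immediate early genes, -1.354 for NF-kB targets and -0.898 for YAP/TEAD targets (adjusted p = 0.00866, 0.0325 and 0.0207 with an estimated correlation). They were 1.629 for integrated stress response genes, 0.831 for hypoxia response genes and 0.327 for p53 targets (0.00205, 0.0325 and 0.0466), and -0.896 for heat shock genes and -0.139 for nuclear oxidative phosphorylation genes (0.00866 and 0.0282). Mitotic and G2/M genes (-0.511), mitochondrially encoded mRNAs (-0.674), cholesterol synthesis genes (-0.113) and glycolysis genes (0.22) passed camera at its preset correlation, but with adjusted p = 0.169, 0.12, 0.0972 and 0.293 when the correlation was estimated.

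Of 50 genes tested that were named by size of change or in the fixed set, 47 differed between the times. The 10 given here were called in opposite directions against 0 h. Genes named only as list members were not counted. Some of them also changed direction, such as ADM and VIM (log2 fold change -0.143 at 1 h and 0.311 at 24 h). The VIM call at 1 h was lost after median-of-ratios scaling (limma adjusted p = 0.102). It was also lost without untreated 0 h replicate 1 (0.0509) or GlyH-101 1 h replicate 2 (0.0555). Higher at 1 h and lower at 24 h were NR4A1, CCN1, FOS, DKK1 and ACTB, with log2 fold changes between the times of -5.412, -5.654, -2.58, -2.385 and -0.68. Lower at 1 h and higher at 24 h were TXNIP, ARL4D, ZNF48, DDIT4 and TRIB3, with 2.813, 1.819, 1.731, 1.625 and 3.192. Groups of 3 libraries were not tested for outlying libraries.

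The luminal transcripts ESR1, GATA3, CDH1, KRT19 and EPCAM were near 0 in libraries labelled MCF-7, while others, such as KRT8, CXXC5 and TBX3, were abundant. If the libraries do not come from a luminal breast line, fewer than 8 of 16 further luminal genes should reach FPKM 5 at 0 h, and 7 did, so that explanation was met by a narrow margin. Loss under the drug is argued against, because the highest of the 5 near-absent genes averaged 0.844 FPKM already at 0 h. A minor admixture of other cells in MCF-7 is argued against by 1.256 FPKM as the highest value of any of the 5 in any library. The values 0.844 and 1.256 restate the pattern, because the 5 genes were picked as near 0, so they are no independent support. Neither explanation alone would give them, however. MCF-7 cells that lost their luminal program are argued against by CDKN2A, at 567.27 FPKM or more in every library although MCF-7 lacks the gene, and which line the cells are was not tested.

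Mitochondrial ribosomal RNA rose at 24 h while mitochondrial mRNA fell. Weaker poly(A) selection would raise RNAs without a poly(A) tail together. The 313 nuclear ones tested had a median log2 fold change of 0.03, so no such general rise was seen. Most of the 313 are small RNAs, and they cannot exclude a technical cause that acts on long RNAs or on rRNA alone. Histone mRNAs fell and lowered that median (-1.065, 28 of 33 lower), but snRNAs and other small RNAs had medians of only 0.251 and 0.143, with upper quartiles of 0.664 and 0.606, far from 1.69 and 2.204 for the 2 rRNAs. The test of a change in the amount of all mitochondrial RNA restates the pattern, so it adds no support. In it 15 of 15 transcripts were called, with the 2 rRNAs up and the 13 mRNAs down. Such a change alone would not give both directions. The ratio of rRNA to mRNA was 0.084 ± 0.003 at 0 h, 0.083 ± 0.001 at 1 h and 0.491 ± 0.027 at 24 h (SD, n = 3, exact p = 0.1 for 24 h against 0 h, the smallest that 3 against 3 can give), and no biological explanation was tested.

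Falls outnumbered rises at 1 h. Scaling between libraries stays open as an explanation. Falls made up 44.8 percent of the calls after median-of-ratios scaling, but that scaling centers the median fold change and so decides nothing, and they made up 57.4 percent after quantile normalization and 57.8 percent after rescaling to TPM. Gene length stays open, since falls were 74.4, 69.1 and 56.1 percent of the calls among short, middle-length and long genes, in 3 groups of nearly equal size. No biological explanation was tested for this balance.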

How the results depend on the processing

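Rescaling to TPM was chosen only after the results were seen, and the other alternatives were fixed beforehand. Over 20 alternatives, 366 counts of genes stayed within 1.5 times and 14 moved further. Median-of-ratios scaling moved the falls at 1 h to 1362. Among genes with a mean of at least FPKM 5, changes by 2-fold or more numbered 134 (124 higher, 10 lower) at 1 h, 301 (181 and 120) at 24 h and 387 (187 and 200) between the times, since fewer genes were tested. Falls by 2-fold or more went to 118 at 1 h and 383 at 24 h with a pseudocount of 0.1, and to 27 and 154 with a pseudocount of 1, which shrinks the folds of low genes. For the other shifts the cause was not tested. Of 329 named-gene results 323 were called; over all alternatives 143 values lost a call, 12 gained one and 0 reversed. Of 84 list results 34 were called; 26 values lost a call, 15 of them with an estimated correlation, 31 gained one, 15 of them without the filter, and 1 reversed, the ribosomal protein genes at 24 h against 0 h after quantile normalization (median 0.063). Without each library in turn, calls ranged from 2634 to 4040 at 1 h, 7891 to 8533 at 24 h and 8246 to 9047 between the times. A replicate block gave 3346, 8548 and 8920 calls and an overlap of 1496. With it glycolysis genes at 24 h no longer passed camera (adjusted p = 0.0528). The block also lost 5 named-gene calls, ARL17B at 1 h among them (limma adjusted p = 0.0512), while DDIT3 at 1 h passed (0.038). Libraries that share a number correlated at -0.054 to 0.088, and not every library correlated best with its own number. In genes near 0, 1 read is a large share of the value.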

Other observations

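The gene groups in this part and their tests were chosen only after the results were seen, though the prediction for ARRDC4 was written before its value was looked at.

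Tubulin genes fell together at 24 h, 9 of 10 tested, with a median log2 fold change of -0.876 (camera adjusted p = 0.0177 with an estimated correlation), and TUBA1B, an alpha-tubulin, went from 391.1 to 139.1 FPKM. All 8 genes of the CCT chaperonin, which folds tubulin and actin, fell (median -0.541, adjusted p = 0.0673 with an estimated correlation). Core clock genes rose in 9 of 11 cases and fell in 1 (adjusted p = 0.119 with an estimated correlation), among them the repressors NR1D1 (from 2.69 to 9.14 FPKM) and NR1D2 (from 11.4 to 43.9). Cytosolic tRNA synthetase genes rose in 12 of 20 cases and fell in 7 (camera adjusted p = 0.156 with an estimated correlation). Of the rises, AARS1, GARS1, SARS1 and WARS1 are members of the integrated stress response list, which had already been tabulated. Mitochondrial tRNA synthetase genes fell in 9 of 17 cases and rose in 1 (camera adjusted p = 0.0673 with an estimated correlation).

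EGF family ligand genes rose at 1 h in 5 of 5 cases tested, EREG by 3.23 and AREG by 3.02 on the log2 scale (camera adjusted p = 0.0177 with an estimated correlation). BTC and EGF lay under the filter, and EPGN was low (0.496 FPKM at 0 h and 1.758 at 1 h). AREG is also a member of a fixed list that had already been tabulated. The hypothesis that ERK feedback genes are higher at 24 h than at 0 h was set after results were seen, and 10 of the 12 feedback genes besides ETV4 and ETV5 were called higher. The 8 of 13 tested genes called higher at 1 h were each called higher at 24 h as well. Their log2 fold changes at 24 h against 0 h ran from 0.877 (EPHA2) to 1.758 (SPRY4). Between 1 h and 24 h 4 of the 13 rose and 5 fell, with IER3 going from 3.85 to 1.014 against 0 h. No time in between was measured, so the count of 10 does not show that a rise at 1 h lasted without a break. The count was also not independent, because CCND1, DUSP4, DUSP6 and IER3 are members of the fixed lists that had already been tabulated. SPRED3 was not called and SPRY1 lay under the filter, while SPRY4 went from 0.431 to 2.68 FPKM and PHLDA1 from 1.37 to 4.84.

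The hypothesis that MondoA targets fall at 1 h stays open, because ARRDC4, the target chosen to test it beside TXNIP, was at 0.284 FPKM at 0 h, under the filter. Handling or vehicle stays open as a cause of either response, because 0 libraries are labelled as vehicle-treated. For each comparison the real grouping gave the highest count (3593, 8622 and 9043) and the other splits of the same 6 libraries gave at most 0. In each comparison the real grouping was 1 of 10 splits, and 10 splits are too few for a share under 0.05. Every other split mixed libraries of both real groups, so the difference between these counted as spread in the fit. Few calls were bound to follow, and the 0 says nothing about the cause of the difference.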
